A study of Mus musculus with 4 samples.

How the data were processed

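The series holds 4 single-cell RNA libraries of tumour-infiltrating immune cells from brain tumours of C57BL/6 mice at the symptomatic stage, 2 from wtIDH1 and 2 from mIDH1 tumours per the labels. The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and barcode, 1 matrix per library. Per the labels' protocols they were made with Cell Ranger 3.1, which aligned reads to mm10 with STAR, counted UMIs and filtered barcodes, whereas per the file headers the software version is 3.0.0. The labels' protocols also describe an aggregation of the runs to equal depth, of which the separate matrices of counts with unequal depth show no sign. The gate or enrichment used to isolate the immune cells is not stated in the labels.

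The libraries wtIDH1 replicate 1 and 2 and mIDH1 replicate 1 and 2 held 3707, 3701, 4708 and 4173 barcodes with totals of 23695857, 22908011, 29849183 and 20908476 UMIs over 31053 genes. Cells with under 200 genes (37, 113, 75 and 101) or over 10% mitochondrial UMIs (550, 587, 923 and 541) were left out. Doublets were scored with Scrublet in scanpy 1.11.5, which called under 0.5% in every library by its automatic threshold, so the highest scores, at the rate expected from the number of barcodes, were removed instead (79, 75, 114 and 104 cells, or 2.52, 2.46, 3.03 and 2.88%). The kept cells numbered 3057, 2980, 3653 and 3507, with medians of 4959, 4869, 3371 and 2700 UMIs and 1979, 1981, 1438 and 940 genes. Xist was read in every library, and Y-linked genes gave at most 17 UMIs in any.

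Counts were scaled to 10000 per cell and logged, and 2000 variable genes, 30 principal components and 15 neighbours went into Leiden clustering at resolution 1.0 (igraph 0.11.9, seed 0). Clusters were named from 21 fixed marker classes, by the number of a class's markers among the 60 top genes of the cluster and by their mean level. The marker lists were fixed before the data were examined, as were the tests, the 37 gene lists and the rule for named genes, while the score limits of the naming were set after the data were seen. The 5 unnamed clusters went into no class comparison. Cluster 6 was named erythroid by this rule from pooled counts, which a few cells rich in hemoglobin set. In the other tested classes 74.6% or more of the cells of every library held 2 or more UMIs of their own markers, against at most 6.61% in cluster 6, a check made after the data were seen. B cell-like and mature dendritic cell-like cells fell short of 30 cells in a library and were not tested for genes.

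UMIs were summed per library and class and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit, trimmed mean normalization, default filter for low counts, threshold 0.05 after Benjamini-Hochberg adjustment). Class shares were tested with edgeR on cell counts for classes with 10 or more cells. The difference between neutrophil-like and macrophage-like cells was tested as an interaction with the library as a block. Fixed lists with 4 or more tested members were tested with camera of limma 3.58.1 at its preset correlation of 0.01, and again with an estimated correlation and with fry. Other versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, matplotlib 3.10.9 and DESeq2 1.42.0. Gene positions are from GENCODE M21 on mm10. Symbols shared by 2 genes, such as Aldoa, were told apart by gene identifier.

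Named genes are, per class, the 10 largest changes in each direction among genes past the threshold whose libraries separate by genotype and whose mean CPM is at least 20. Up to 4 members of a fixed list with the lowest p may be named with that list, and 22 genes fixed in advance are given in the 4 myeloid classes whatever their result. For the difference between classes the genes of lowest p are named, a choice made after the data were seen. Predicted genes are counted but not named.

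The tests were tested on simulated data made from the real sums with changes added. A change of 2-fold was found in 4.48% of neutrophil-like, 43.3% of monocyte-like, 56.7% of macrophage-like, 14.9% of microglia-like, 29.9% of cDC2-like, 44.8% of T cell-like, 29.9% of NK cell-like and 13.4% of cluster 6 genes so changed. For 4-fold the shares were 65.2, 95.5, 95.5, 74.2, 83.3, 90.9, 80.3 and 68.2%. Unchanged genes called numbered 13, 10, 11, 3, 3, 10, 6 and 3. As a share of all genes called they exceeded the threshold of 0.05 in every class but microglia-like and cDC2-like cells. In neutrophil-like cells the 13 stood beside 0, 3 and 43 changed genes found at 1.5-fold, 2-fold and 4-fold. In monocyte-like cells the 10 stood beside 9, 29 and 63. In all cells summed 28.4% and 75.8% were found at 2-fold and 4-fold (19 and 50 genes), and 0 genes at 1.5-fold. There 24 unchanged genes were called, a share that also exceeded 0.05. The interaction, simulated on the 7275 genes tested in both classes rather than the 10905 of the real test, found 7.46% and 51.5%, with 3 unchanged genes called. An 8-fold change of the neutrophil-like share was found in 85 of 100 draws, with 14 of 1200 unchanged shares called. In these draws the other shares were not lowered as the neutrophil-like share rose. The 14 therefore do not cover calls that arise because shares add up to the whole. A list shifted by 2-fold was found by camera at its preset correlation in all 8 classes. In the same class order, unshifted lists called numbered 0 of 31, 0 of 33, 2 of 34, 2 of 32, 2 of 32, 1 of 32, 0 of 26 and 1 of 27. Genes were drawn independently, so this cannot show how the preset performs where the members of a list vary together. With an estimated correlation the adjusted p of the shifted list ran from 0.142 to 0.526, so that version of the test has little power here.

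Alternatives were DESeq2, other scalings, no filter for low counts, sums thinned to equal depth, the replicate number as a block, leaving out each library, other cell filters, doublets kept, Leiden resolutions of 0.5 and 2.0, and monocyte-like and macrophage-like cells summed together. After the data were seen, subtraction of RNA of other cells, a wider neutrophil-like class, tests of each cluster alone and fits of the shares without neutrophil-like cells that leave out 1 library were added. The subtraction first used the profile of all cells of a library, which took up to 96.4% of the UMIs of a sum, and was then redefined with the profile of neutrophil-like cells (for neutrophil-like cells, of all other cells). Its size was set from Retnlg, Ngp, Camp, Ltf, Wfdc21 and Stfa2l1 (for neutrophil-like cells, from C1qa, C1qb, C1qc and Apoe).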

Results

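Tumour-infiltrating immune cells of mouse brain tumours with wild-type IDH1 (wtIDH1) or mutant IDH1 (mIDH1) were profiled by single-cell RNA sequencing at the symptomatic stage. IDH1 is a metabolic enzyme whose mutant form makes D-2-hydroxyglutarate, and each genotype had 2 libraries. Of 16289 barcodes, 13197 cells were kept, and 22 of 27 clusters were named as cell classes from marker genes. Each class was summed per library and tested as mIDH1 against wtIDH1, so positive log2 fold changes mean higher in mIDH1. Levels are means ± SD (n = 2) in CPM, UMIs scaled to the class's own UMI sum. Log2 fold changes follow normalization and so differ from the ratio of the CPM values. A single number in brackets after a gene, or the number that follows its CPM values, is its log2 fold change, and every gene said to rise or fall passed adjusted p < 0.05. With 2 libraries against 2 no exact permutation p can fall under 0.333, so the adjusted p-values rest on the variance model of edgeR. They measure only the spread between these samples, since the labels do not say that the libraries come from separate animals. Idh1 itself (chr1:65158616–65186500 in mm10) gave 793 and 1158 UMIs in the wtIDH1 libraries and 1567 and 932 in the mIDH1 libraries. Such counts do not tell mutant from wild-type transcripts.

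Neutrophil-like cells, short-lived granulocytes whose production is driven by G-CSF, made up 3.76% and 6.71% of the wtIDH1 libraries and 30.4% and 50.6% of the mIDH1 libraries. The 95% Wilson intervals were 3.14 to 4.50, 5.87 to 7.67, 28.9 to 31.9 and 49.0 to 52.3. They cover counting error within a library only and not the spread between libraries of a genotype. The mean share was 5.24 ± 2.09% in wtIDH1 and 40.5 ± 14.3% in mIDH1, a ratio of 7.73. Its log2 fold change of 2.95 (SE 0.64) missed the threshold of 0.05 (adjusted p = 0.0503). It passed under several alternatives, such as trimmed mean normalization (3.52, adjusted p = 0.0256), but in none of the 4 fits that leave out 1 library. The cDC2-like cells, dendritic cells that present antigen to CD4 T cells, were the only class whose share passed. They fell from 5.40 ± 0.0432% to 1.65 ± 0.0475% (log2 fold change −1.71, SE 0.19, adjusted p = 0.00726). Monocyte-like cells were at 20.1 ± 6.15% and 7.85 ± 0.0684%, and NK cell-like cells at 7.81 ± 2.41% and 3.32 ± 0.906%. Cluster 6 was at 9.17 ± 2.51% and 4.13 ± 0.967%, and mast cell-like or basophil-like cells at 0.0986 ± 0.0919% and 1.08 ± 0.561%. For each of these 4 classes the adjusted p = 0.0503. The marker rule named cluster 6 erythroid, but only 13 of its 849 cells held 10 or more hemoglobin UMIs, all of them in the replicate 2 libraries. It is therefore given by its number, and what its other cells are was not settled. T cell-like cells (15.04 ± 0.0567% and 11.1 ± 5.29%), macrophage-like cells (17.1 ± 3.64% and 12.8 ± 2.87%) and microglia-like cells (7.95 ± 0.278% and 5.91 ± 3.52%) did not pass (adjusted p = 0.542 each).

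**Figure D1:**
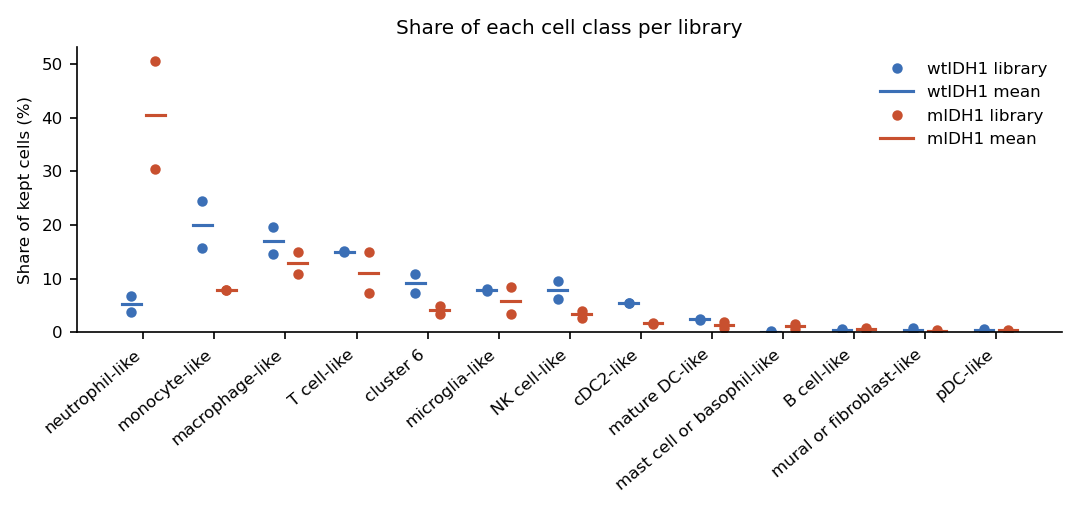
Share of each named class among the kept cells of each library (dots) and their mean (bars). Cluster 6 was named erythroid by its markers, which few of its cells carry. The cDC2-like share passed the main edgeR test and the neutrophil-like share missed it.

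Shares add up to the whole, so a large class lowers the others. With neutrophil-like cells left out of the total, the cDC2-like share was 5.70% and 2.86% (log2 fold change −1.003, adjusted p = 0.342). That log2 fold change stayed negative with any 1 library left out, from −0.74 without mIDH1 replicate 1 to −1.295 without mIDH1 replicate 2. Macrophage-like cells then made up 18.1% and 21.6%. Only the mast cell-like or basophil-like share then rose (0.103 ± 0.0947% to 1.75 ± 0.521%, log2 fold change 4.02, adjusted p = 0.0264). It rests on 5 and 1 wtIDH1 cells, and it was lost with any 1 library left out (3.33 to 5.42, adjusted p = 0.0922 to 0.308). The cDC2-like call was lost without wtIDH1 replicate 1 (−1.70, adjusted p = 0.147) and without wtIDH1 replicate 2 (−1.72, adjusted p = 0.1004). It was also lost with cells of at most 5% mitochondrial UMIs (−1.60, adjusted p = 0.0696) and with the replicate number as a block (−1.71, adjusted p = 0.133). The exact permutation p was 0.333 for the neutrophil-like, cDC2-like, monocyte-like, T cell-like and NK cell-like shares, 0.667 for the macrophage-like share and 1 for the microglia-like share. No barcode held under 500 UMIs. Neutrophil-like cells lie nearer to that limit than macrophage-like cells, with library medians of 1552 to 2199 UMIs against 9891 to 11381. Unnamed clusters held 8.18% and 8.99% of cells. Among them cluster 20 scored nearest to neutrophils under a score limit set after the data were seen, and held 2 and 11 wtIDH1 cells and 87 and 44 mIDH1 cells.

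In neutrophil-like cells 18 genes rose and 11 fell of 7394 tested. Among the rises was that of Stfa1 (chr16:36276951–36285373), a stefin that blocks cysteine proteases (3.63 ± 0.985 to 158 ± 94.5 CPM, log2 fold change 5.82, SE 0.61, adjusted p = 0.000697). Its wtIDH1 level is 1 UMI in each library, so the size of that fold is not well fixed. The related Stfa2l1 also rose (386 to 1228 CPM, 2.21). Wfdc17, a small secreted protein of activated myeloid cells, rose (845 ± 76.3 to 5058 ± 2788 CPM, log2 fold change 3.16, SE 0.55, adjusted p = 0.0312). The acute phase gene Saa3 (67.2 to 271 CPM, 2.55) and the chaperones Hspa1a (61.1 to 373 CPM, 2.97) and Hspa1b (3.88) rose. So did Hilpda, which is induced by hypoxia and coats lipid droplets (341 to 980.1 CPM, 2.03), Upp1, which breaks down uridine (2.19), and the cytokine Il1a (105 to 299.8 CPM, 1.96). Irf8 (chr8:120736358–120756694), a transcription factor of the monocyte and dendritic cell lineages, fell (129 ± 4.60 to 27.5 ± 13.04 CPM, log2 fold change −1.85, SE 0.34, adjusted p = 0.0312). The matrix protein Thbs1 fell (1215 ± 43.1 to 283 ± 45.0 CPM, log2 fold change −1.66, SE 0.33, adjusted p = 0.0427). The scavenger chemokine Cxcl16 (140.3 to 24.1 CPM, −2.21), the MHC class I gene H2-Q6 (−2.001), the ERK phosphatase Dusp6 (−1.84), the immediate early gene Nr4a1 (−1.78) and the receptor Notch1 (−1.58) fell as well.

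Among the fixed lists, the glycolysis genes had the lowest p in neutrophil-like cells (camera adjusted p = 4e-10). Their median log2 fold change was 0.93 over 18 members, none past the threshold over all genes and 13 past it when adjusted over the list alone. Inflammatory cytokines and chemokines had a median of 1.09, with Il1a up, Cxcl16 down and 11 of 18 past it adjusted over the list alone (adjusted p = 1.78e-06). The hypoxia response list had a median of 0.47, with 2 of 20 up, Hilpda among them, and 5 adjusted over the list alone (adjusted p = 0.000239). With an estimated correlation the adjusted p = 0.763 for these 3 lists. The G-CSF and STAT3 response list had a median of 0.35 that turned to −0.10 with library totals as the only scaling. Of its 17 members none passed and 1 passed adjusted over the list alone (adjusted p = 0.0212, passing in 2 of the 4 fits that leave out 1 library). With an estimated correlation that list had an adjusted p = 0.867. Immunosuppressive mediators (median 0.09 over 15 members, adjusted p = 0.417), neutrophil granule genes (0.37 over 16, adjusted p = 0.527) and mature neutrophil genes (0.24 over 16, adjusted p = 0.218) did not pass. With library totals alone these medians turned to −0.35, −0.15 and −0.26.

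Several genes fixed in advance did not pass in neutrophil-like cells, and their brackets hold the log2 fold change and the adjusted p. The alarmins S100a8 (16248 and 38375 CPM, 1.82, 0.194) and S100a9 (16316 and 44361 CPM, 2.04, 0.173) and the G-CSF receptor Csf3r (2594 and 1318 CPM, −0.53, 0.502) were among them. So were the chemokine receptor Cxcr2 (−0.07, 0.948), the cytokines Il1b (1.001, 0.307), Tnf (1.06, 0.153) and Tgfb1 (0.53, 0.434), and Arg1 (−0.29, 0.679) and Nos2 (1.72, 0.107), which consume arginine. The PD-L1 gene Cd274 (0.98, 0.175), the interferon-induced Isg15 (1.20, 0.177), Vegfa (−0.22, 0.821), Spp1 (0.47, 0.498) and Apoe (−0.10, 0.943) did not pass. Neither did the antigen presentation genes Cd74 (0.18, 0.829) and H2-Aa (−0.24, 0.807) or Idh1 (−1.34, 0.296). Idh2, Csf3, Il10, Ifng and Pdcd1 had too few counts to test.

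The neutrophil-like class joins clusters whose mix differs between the libraries. Cluster 1, led by F3, Hcar2 and Cxcl2, held 35 and 34 wtIDH1 cells and 445 and 746 mIDH1 cells. Cluster 2, led by Mmp9, Cxcr2 and Csf1, held 54, 133, 466 and 393 in the same order, and cluster 5, led by the granule genes Ngp, Camp and Ltf, held 26, 33, 198 and 636. Within cluster 1 alone 7 genes rose and 6 fell of 3557, among them Wfdc17 (2.83) and S100a8 (2.30) up and Thbs1 (−2.91) down. Within cluster 2 alone 39 rose and 28 fell of 6169, among them Wfdc17 (2.62) and Saa3 (3.08) up and Irf8 (−1.78) and Cxcl16 (−2.18) down. Stfa1 had no wtIDH1 count in either cluster. RNA of other cells was estimated at 33.4% and 25.3% of the UMIs of the wtIDH1 sums and 29.9% and 9.65% of the mIDH1 sums. After its subtraction 0 of 5601 genes passed, and 694 had p under 0.05. The adjusted p-values rose while the folds kept their direction, as for Stfa1 (log2 fold change 5.73, SE 0.73, adjusted p = 0.2325), Wfdc17 (2.95, SE 0.52), Thbs1 (−2.20, SE 0.26) and H2-Q6 (−3.29, SE 0.43). Irf8 and Cxcl16 had too few counts left to test, as the subtraction took most of their counts for RNA of other cells. Their falls in the class, and within cluster 2 where no subtraction was made, are thus not shown to lie in neutrophil-like cells. The count was 829 without mIDH1 replicate 1, 259 without mIDH1 replicate 2, 79 without wtIDH1 replicate 1 and 36 without wtIDH1 replicate 2. Of 23 genes open to naming 22, 22, 16 and 11 still passed. Wfdc17, Stfa2l1, Upp1, Hilpda and Thbs1 were lost without either wtIDH1 replicate, Il1a and Nr4a1 without wtIDH1 replicate 1, and Saa3, Notch1 and Dusp6 without wtIDH1 replicate 2. DESeq2 called 169 genes, 25 of the 29 among them, and library totals alone gave 61 up and 185 down. All 29 genes separated the libraries of the genotypes, as did 49.9% of all tested genes (33.3% by chance). Separation was judged on CPM of library totals, where a shift shared by many genes also separates the libraries. Genes of low p separate almost of themselves. Here and below these shares are therefore no test of genotype.

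In macrophage-like cells 805 genes rose and 265 fell of 10695. Arg1 (chr10:24915221–24927484), which depletes arginine and marks suppressive myeloid cells, rose (3788 ± 699 to 9046 ± 61.5 CPM, log2 fold change 1.55, SE 0.24, adjusted p = 0.0133). Nos2, which makes nitric oxide from arginine, rose as well (64.2 ± 38.3 to 311 ± 19.1 CPM, log2 fold change 2.58, SE 0.38, adjusted p = 0.0119). So did Spp1, which encodes osteopontin (2015 ± 302 to 4091 ± 295 CPM, log2 fold change 1.32, SE 0.21, adjusted p = 0.0135). Chil3, a lectin of recruited myeloid cells (219 to 3778 CPM, 4.44), the folate receptor Folr2 (3.51 to 47.1 CPM, 4.05), the uridine enzyme Upp1 (16.9 to 159 CPM, 3.56) and the transcription factor Klf2 (44.2 to 177 CPM, 2.30) rose. The calcium-binding S100a4 rose (73.0 ± 26.6 to 607 ± 116 CPM, log2 fold change 3.36, SE 0.32, adjusted p = 0.00447). The iron exporter Slc40a1 (75.8 to 3.97 CPM, −3.87), the TGF-beta receptor Tgfbr1 (137 to 33.5 CPM, −1.74) and the fractalkine receptor Cx3cr1 (156 to 38.6 CPM, −1.71) fell. The semaphorin receptor Plxnc1 (−1.82), the protease Adamdec1 (−4.10), the glutathione enzyme Gstm1 (−1.73) and the phagocytic receptor Axl (−1.52) also fell.

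Genes of the hypoxia response and of glycolysis moved together in macrophage-like cells. Of 22 hypoxia genes 19 rose and none fell, and 21 passed adjusted over the list alone (median log2 fold change 1.42, camera adjusted p = 4.5e-23). Among them were Hilpda (119 ± 11.7 to 594 ± 175 CPM, log2 fold change 2.63, SE 0.27, adjusted p = 0.00447), the oxygen sensor Egln3 (77.2 to 269.9 CPM, 2.11), Ankrd37 (14.5 to 70.9 CPM, 2.60) and Fam162a (60.8 to 190.2 CPM, 1.95). Of 18 glycolysis genes 17 rose, and 18 passed adjusted over the list alone (median 1.09, adjusted p = 1.89e-17). They include lactate dehydrogenase Ldha (654 ± 71.1 to 1294 ± 93.6 CPM, log2 fold change 1.29, SE 0.21, adjusted p = 0.0140), enolase Eno1 (357 to 962 CPM, 1.74), hexokinase Hk1 (1.21) and phosphofructokinase Pfkp (1.23). Inflammatory cytokines and chemokines had 13 up and 1 down of 19, and 16 adjusted over the list alone (median 1.71, adjusted p = 3.4e-14). The monocyte attractants Ccl7 (147 to 1029 CPM, 3.14) and Ccl8 (39.0 to 292 CPM, 3.19) and the chemokines Ccl6 (1163 to 3717 CPM, 1.97) and Ccl9 (276 to 1251 CPM, 2.48) rose. For each of these 3 lists the adjusted p = 0.640 with an estimated correlation.

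Other fixed lists moved in the macrophage-like class as well, and their medians within its clusters are given below. Of 17 immunosuppressive mediators 5 rose, among them Nos2, Arg1, the adenosine-producing Nt5e (0.92) and the prostaglandin enzyme Ptgs2 (1.32), and Il10 fell (2.93 to 0.378 CPM, −2.70). For that list 13 passed adjusted over the list alone (median 0.59, adjusted p = 0.000261). Genes of cholesterol synthesis and uptake had 6 of 18 up and 14 adjusted over the list alone (median 1.07, adjusted p = 1.13e-06), with Sqle (2.68). Of 19 homeostatic microglia genes 6 fell and 9 passed adjusted over the list alone (median −0.61, adjusted p = 0.000754), with Tgfbr1, Cx3cr1 and P2ry13 (−1.15). With an estimated correlation these lists too had an adjusted p = 0.640. MHC class II genes (median 0.12 over 13, −0.18 with library totals alone, adjusted p = 0.648) did not pass as a list. Neither did the type I interferon response (0.24 over 28, −0.05 with library totals alone, adjusted p = 0.155).

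Neutrophil genes rose in the same sums. All 6 genes of the list made for neutrophil RNA were up in macrophage-like cells (median 3.77, adjusted p = 9.27e-10; adjusted p = 0.640 with an estimated correlation). S100a8 (106 to 835 CPM, 3.31) and S100a9 (86.7 to 972 CPM, 3.83) rose, and after subtraction of neutrophil RNA their log2 fold changes were 0.13 and 1.26 and did not pass. Wfdc21 of the same list stayed at 5.08 (adjusted p = 0.0153). It is one of the genes that set the size of the subtraction. What is left of it may reflect a ratio of these genes unlike that in neutrophil-like cells. It does not show expression by macrophage-like cells. Of the 1070 calls, 988 passed again after that subtraction. Cxcr2 rose (15.1 to 43.1 CPM, 1.81) but not after the subtraction (1.05, adjusted p = 0.475), and the invariant chain Cd74 rose (2293 to 3329.9 CPM, 0.83). Not passing, with the log2 fold change and the adjusted p, were Il1b (0.63, 0.169), Tnf (−0.09, 0.720), Cd274 (0.67, 0.0601), Tgfb1 (0.59, 0.0940), Vegfa (0.73, 0.125) and Apoe (−0.15, 0.681). The same holds for H2-Aa (0.42, 0.232), Isg15 (1.17, 0.152), Csf3r (0.14, 0.617), Idh1 (0.38, 0.260) and Idh2 (−0.44, 0.176). Csf3, Ifng and Pdcd1 had too few counts.

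Macrophage-like cells came from clusters 3 and 4, and the balance between them differed by genotype. Cluster 3, led by Gpnmb, Apoe and Hmox1, held 362 and 513 wtIDH1 cells and 99 and 42 mIDH1 cells. Cluster 4, led by Ccl7, Arg1, Mrc1 and Chil3, held 82 and 73 wtIDH1 cells and 444 and 337 mIDH1 cells. Arg1, Chil3, Ccl7, Ccl8, Ccl9, Adamdec1 and Gstm1 are leading genes of one of these clusters, so their class values carry that balance. Spp1 is a marker among the 60 top genes of cluster 4, so its class value carries that balance too. Within cluster 3 alone 251 genes rose and 50 fell of 9926, and within cluster 4 alone 5 rose and 3 fell of 8967. Arg1 stood at 3315 and 4288 CPM in cluster 3 (log2 fold change 0.60, adjusted p = 0.293) and at 7649 and 10210 CPM in cluster 4 (0.60, adjusted p = 0.209). Nos2 rose from 28.8 to 148 CPM in cluster 3 (2.63) and stood at 333 and 352 CPM in cluster 4 (0.25, adjusted p = 0.608). S100a4 rose (1.65 and 1.85) and Itgax fell (−0.88 and −1.37) in clusters 3 and 4 alike. Folr2 (4.08), Hilpda (1.09), Ccl8 (4.06), Cd74 (2.01) and H2-Aa (1.72) rose in cluster 3. In cluster 4 these 5 genes did not pass, with log2 fold changes of 1.78, 0.85, 0.97, 0.19 and −0.31. The hypoxia list median was 0.44 in cluster 3 and 0.09 in cluster 4, and the glycolysis median 0.55 and 0.24. In the same order the medians were 0.33 and 0.84 for inflammatory genes and 0.10 and 0.13 for immunosuppressive mediators. They were 0.63 and 0.36 for cholesterol synthesis and uptake and 0.22 and −0.09 for homeostatic microglia genes. The class medians of these lists thus carry the cluster balance. MHC class II genes had 7 of 13 up and 1 down in cluster 3 (median 0.88) and 0 of 12 up in cluster 4 (−0.17).

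**Figure D2:**
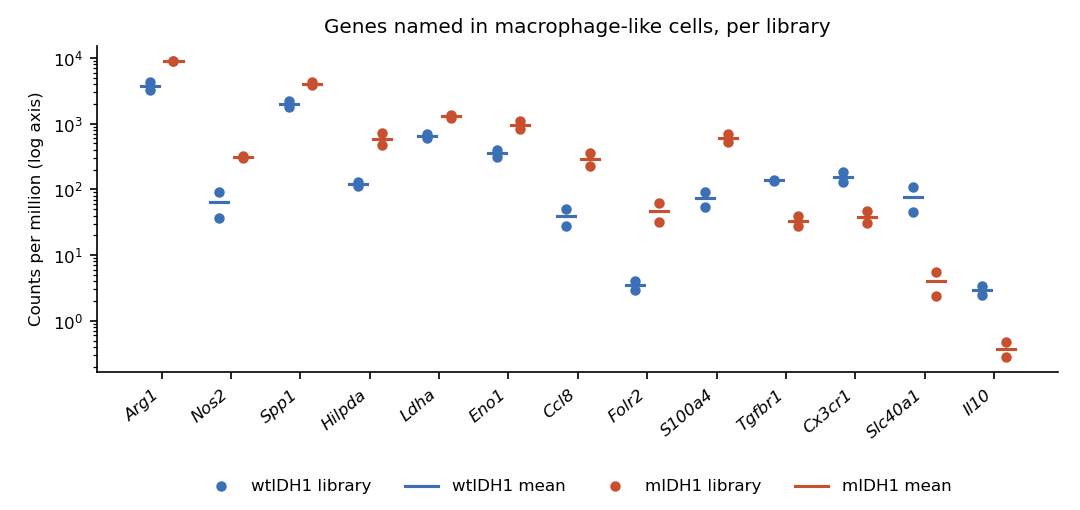
Genes in macrophage-like cells of each library, in CPM of the class sum on a log axis. The class joins clusters 3 and 4, whose balance differs between the genotypes.

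All 1070 genes called in macrophage-like cells separated the libraries of the genotypes, as did 71.3% of all tested genes (33.3% by chance). The count was 1838 without mIDH1 replicate 1, 397 without mIDH1 replicate 2 and 580 without wtIDH1 replicate 2. Of 97 genes open to naming 91, 68 and 79 still passed. Among the genes above, Adamdec1, Sqle, Ptgs2 and Cxcr2 were lost without mIDH1 replicate 2 and Nt5e without wtIDH1 replicate 2. Cd74 was lost without either wtIDH1 replicate and Il10 without any 1 of the 4 libraries. Library totals as the only scaling gave 520 up and 1233 down.

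In monocyte-like cells 493 genes rose and 200 fell of 9519, with cholesterol synthesis genes among them. Of 17 genes of cholesterol synthesis and uptake 13 rose, and 15 passed adjusted over the list alone (median log2 fold change 1.40, camera adjusted p = 2.71e-16). They include the sterol demethylase Cyp51 (18.6 to 64.3 CPM, 2.09) and the sterol carrier Stard4 (7.38 to 22.5 CPM, 1.87). Fdps of the same list, which makes farnesyl diphosphate, rose too (10.3 ± 2.63 to 66.7 ± 45.5 CPM, log2 fold change 2.99, SE 0.45, adjusted p = 0.00550). Within cluster 0 the list had a median of 1.57 with 12 of 17 up, and within cluster 13 a median of 0.28 with 0 of 12 up. Oxidative phosphorylation genes had 15 of 26 up and 19 adjusted over the list alone (median 0.97, adjusted p = 2.97e-15), with the cytochrome oxidase subunit Cox5b (1.497). Interferon gamma response genes had 5 of 20 up and 6 adjusted over the list alone (median 0.34, adjusted p = 8.31e-05). Among these were the T cell attractant Cxcl9 (629 ± 24.5 to 1812 ± 241 CPM, log2 fold change 1.77, SE 0.26, adjusted p = 0.00550) and Socs1 (1.30). With an estimated correlation the adjusted p = 0.667 for these 3 lists. Inflammatory cytokines and chemokines had 7 of 18 up and 12 adjusted over the list alone (median 0.92, adjusted p = 1.4e-07), with Cxcl3 (2.42) and Ccl9 (1.17). For that list the adjusted p = 0.610 with an estimated correlation.

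Hp, which encodes haptoglobin (112 to 421 CPM, 2.15), the matrix proteoglycan Vcan (1.76), Chil3 (992 to 3626 CPM, 2.11), the acute phase gene Saa3 (23.5 to 200.2 CPM, 3.31) and Dmkn (7.30 to 97.9 CPM, 3.98) rose in monocyte-like cells. The class joins cluster 0 (657 and 387 wtIDH1 cells, 192 and 183 mIDH1 cells) and cluster 13 (89, 81, 93 and 94), so its values carry a larger part of cluster 13 in mIDH1. Hp (1.71 and 1.55) and Vcan (1.85 and 0.89), which mark cluster 13, rose within clusters 0 and 13 alike. The phagocytic receptor Axl (chr7:25757273–25788705) fell (378 ± 30.7 to 101 ± 15.6 CPM, log2 fold change −1.67, SE 0.21, adjusted p = 0.00261). The related receptor Mertk (74.0 to 18.1 CPM, −1.81), the decoy receptor Il1r2 (711 to 154 CPM, −1.96), the elastase Mmp12 (339.9 to 54.2 CPM, −2.41), the cyclin Ccnd2 (−1.81) and Plxnc1 (−1.98) fell as well. Nos2 rose (39.1 to 176 CPM, 2.31). Il10 had 54 counts in wtIDH1 and 0 in mIDH1, at least 8.78-fold lower against a floor of 3 counts. Arg1 (1111 and 1344 CPM, 0.48, 0.388), Il1b (0.60, 0.192), Tnf (0.01, 0.981), Cd274 (0.57, 0.208), Tgfb1 (0.18, 0.654), Vegfa (−0.42, 0.2498) and Spp1 (0.36, 0.606) did not pass (log2 fold change, adjusted p). Neither did Apoe (0.25, 0.635), H2-Aa (−0.07, 0.897), Cd74 (0.43, 0.390), Isg15 (0.38, 0.532), Csf3r (0.45, 0.257), Idh1 (0.09, 0.843) and Idh2 (−0.45, 0.455). Csf3, Ifng and Pdcd1 had too few counts.

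Neutrophil genes rose in monocyte-like cells too, with all 6 genes of that list up (median 4.004, adjusted p = 9e-28; adjusted p = 0.492 with an estimated correlation). Retnlg (2.42 to 84.6 CPM, 5.32), S100a8 (102 to 1196 CPM, 3.77) and S100a9 (96.0 to 1235 CPM, 3.91) rose. After subtraction of neutrophil RNA the log2 fold change of S100a8 turned to −0.51 and S100a9 was left with no mIDH1 count, while 636 of the 693 calls passed again. Retnlg (5.47, adjusted p = 0.00514) and Wfdc21 (3.64, adjusted p = 0.00465) of the same list stayed up. Both are among the genes that set the size of the subtraction, so what is left of them does not show expression by monocyte-like cells. Cxcr2 rose (18.3 to 51.2 CPM, 1.72) but not after the subtraction (0.03, adjusted p = 0.985). The hypoxia list had a median of 0.13 that turned to −0.10 with library totals alone, with 5 of 20 up and 8 adjusted over the list alone (adjusted p = 0.0111). For that list the adjusted p = 0.668 with an estimated correlation. All 693 calls separated the libraries, as did 61.8% of tested genes (33.3% by chance). The count was 77 without mIDH1 replicate 2, and of 77 genes open to naming 32 still passed. Cyp51, Stard4, Chil3, Mmp12, Socs1, Il10 and Nos2 were lost there, Nos2 also without mIDH1 replicate 1. Library totals alone gave 426 up and 914 down.

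In microglia-like cells 89 genes rose and 13 fell of 8054. The class joins cluster 9 and cluster 18, whose cells are deeper (medians of 1113 and 8600 UMIs). Cluster 18 gave 56.8% and 76.2% of the class UMIs in wtIDH1 and 71.1% and 40.9% in mIDH1, and the clusters were not tested apart. Apoe (chr7:19696109–19699188), the main lipid carrier of the brain, rose (7892 ± 331 to 32264 ± 6366 CPM, log2 fold change 2.30, SE 0.35, adjusted p = 0.00124). Spp1 (475 to 2275 CPM, 2.55), the apolipoprotein Apoc4 (12.01 to 105 CPM, 3.404), Nos2 (10.6 to 102 CPM, 3.63) and Saa3 (117 to 1972 CPM, 4.34) rose. So did the chemokines Ccl8 (32.1 ± 6.73 to 665 ± 56.5 CPM, log2 fold change 4.66, SE 0.39, adjusted p = 2.16e-06) and Ccl5 (283 to 1385 CPM, 2.58). The iron exporter Slc40a1 (93.6 to 5.45 CPM, −3.27), the protease inhibitor Serpine2 (173 to 20.5 CPM, −2.75), the heme oxygenase Hmox1 (848 to 209 CPM, −1.74) and the integrin Itgax (−1.86) fell. Of 12 MHC class II presentation genes 4 rose, namely Cd74 (1326 to 3409.6 CPM, 1.65), H2-Aa (506 to 1204 CPM, 1.53), H2-Eb1 (1.94) and H2-Ab1 (1.40). For that list 6 passed adjusted over the list alone (median 0.72, camera adjusted p = 3.17e-07). The interferon gamma response list had 1 of 19 up and 9 adjusted over the list alone (median 0.64, adjusted p = 1.42e-07). For these 2 lists the adjusted p = 0.409 with an estimated correlation. The disease-associated and lipid-handling list had 3 up and 1 down of 20 and 10 adjusted over the list alone (median 0.66, adjusted p = 0.00023; adjusted p = 0.457 with an estimated correlation). None of 20 homeostatic microglia genes passed and 3 did adjusted over the list alone (median −0.36, adjusted p = 0.0198; adjusted p = 0.742 with an estimated correlation). That list passed in 2 of the 4 fits that leave out 1 library.

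Neutrophil genes moved with genotype in microglia-like cells too, with 5 of 5 genes up (median 4.49, adjusted p = 1.13e-27; adjusted p = 0.247 with an estimated correlation). S100a8 (4.65), S100a9 (4.49) and Cxcr2 (2.30) rose. After subtraction of that RNA, estimated at 10.4% of the UMIs of mIDH1 replicate 1, 27 genes passed, 25 of them among the 102. These include Ccl8, Ccl5, Saa3, Nos2, Apoc4, Apoe, Spp1, Cd74, H2-Eb1, Slc40a1, Serpine2 and Hmox1. H2-Aa (1.60, adjusted p = 0.0766), H2-Ab1, Itgax and Cxcr2 were lost, as were S100a8 (4.18, adjusted p = 0.309) and S100a9 (3.94, adjusted p = 0.377). What is left of S100a8 and S100a9 rests on mIDH1 replicate 2, where 1.65% of the UMIs was subtracted. In mIDH1 replicate 1 the subtraction takes nearly all of both. There S100a8 stood at 2373 CPM here and 22764 CPM in neutrophil-like cells, and S100a9 at 2333 and 23496 CPM. Il1b (1.60, 0.0991), Tnf (0.31, 0.802), Arg1 (1.20, 0.329), Cd274 (1.33, 0.0509) and Tgfb1 (0.32, 0.755) did not pass (log2 fold change, adjusted p). Neither did Vegfa (0.18, 0.908), Isg15 (0.25, 0.831), Csf3r (0.30, 0.769), Idh1 (0.30, 0.8004) and Idh2 (−0.77, 0.478). Csf3, Il10, Ifng and Pdcd1 had too few counts. Of the 102 calls 101 separated the libraries, as did 51.0% of tested genes (33.3% by chance). The count was 370 without mIDH1 replicate 1, 54 without mIDH1 replicate 2 and 261 without wtIDH1 replicate 1. Of 46 genes open to naming 36, 27 and 41 still passed, and 29 without wtIDH1 replicate 2. Apoe, Cd74, H2-Aa, H2-Eb1 and H2-Ab1 were lost without wtIDH1 replicate 2, Nos2 without mIDH1 replicate 1 and Hmox1 and Itgax without mIDH1 replicate 2. Library totals alone gave 57 up and 27 down.

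In T cell-like cells 507 genes rose and 160 fell of 9690, type I interferon response genes among the latter. Of 28 type I interferon response genes 12 fell and none rose, and 23 passed adjusted over the list alone (median log2 fold change −0.81, camera adjusted p = 7.46e-15). Ifit1 (chr19:34640871–34650009), which binds viral RNA, fell (153 ± 34.6 to 36.9 ± 20.2 CPM, log2 fold change −1.73, SE 0.27, adjusted p = 0.00732). Rsad2, which encodes the antiviral enzyme viperin (96.7 to 22.5 CPM, −1.78), the RNA sensor Ddx58 (−0.96) and Cmpk2 (−1.64) fell. The granzymes Gzme (39.2 ± 1.96 to 4.87 ± 2.68 CPM, log2 fold change −2.60, SE 0.30, adjusted p = 0.00224) and Gzmd (45.9 to 7.13 CPM, −2.41), proteases of cytotoxic granules, fell. The granzyme B inhibitor Serpinb9 fell (322 ± 19.5 to 77.0 ± 3.81 CPM, log2 fold change −1.80, SE 0.17, adjusted p = 0.00108), as did the nucleotide reductase Rrm2 (−1.53) and Il10 (−1.48). The chemokine Ccl5 rose (500.1 ± 80.5 to 1586 ± 264 CPM, log2 fold change 1.94, SE 0.22, adjusted p = 0.00224). The granule protein Nkg7 (1000.1 to 1773 CPM, 1.10), Cst7 (109.8 to 182 CPM, 0.996) and the granzyme Gzmc (1.83) rose. With Ccl5 they count among the 5 of 19 cytotoxicity genes that rose, 8 adjusted over the list alone (median 0.41, adjusted p = 0.00757). Oxidative phosphorylation genes had 12 of 26 up and 20 adjusted over the list alone (median 0.63, adjusted p = 5.62e-14). With an estimated correlation the adjusted p = 0.727 for these 3 lists. None of 14 exhaustion genes passed (median −0.05, adjusted p = 0.860).

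T cell-like cells came from 4 clusters, of which cluster 7, led by Cd4 and Tcf7, held 285 and 220 wtIDH1 cells and 200 and 124 mIDH1 cells. Cluster 11, led by Cd8a, Gzmf and Nkg7, held 62 and 121 wtIDH1 cells and 218 and 93 mIDH1 cells, and Nkg7 in the class carries that balance. Cluster 15, led by the cell cycle genes Pclaf, Mki67 and Rrm2, held 50, 77, 67 and 15 cells in the same order, so Rrm2 in the class carries its share. Cluster 19, led by Ikzf2 and Foxp3, held 64, 29, 58 and 27. Ifit1 (−2.30 and −1.39) and Serpinb9 (−1.32 and −2.21) fell in clusters 7 and 11 alike, and Ccl5 rose in both (1.58 and 2.16). Rsad2 fell in cluster 7 (−2.19) and did not pass in cluster 11 (−1.20, adjusted p = 0.0734). Gzme (−2.82) and Gzmd (−3.30) fell and Nkg7 rose (1.01) in cluster 11. The cytotoxicity list had medians of −0.04 in cluster 7 and 0.18 in cluster 11, so its class median carries the cluster balance. The exhaustion list had medians of −0.56 in cluster 7, with 1 of 12 genes down, and −0.27 in cluster 11, with 0 of 13 down. Its class median near 0 thus carries that balance too. Neutrophil RNA moved here too, with S100a8 (13.1 to 96.6 CPM, 3.13) and S100a9 (2.71) up. Of the 667 calls 664 separated the libraries, as did 64.1% of tested genes (33.3% by chance). The count was 1811 without mIDH1 replicate 1, 377 without wtIDH1 replicate 1 and 244 without wtIDH1 replicate 2. Of 66 genes open to naming 63, 47 and 40 still passed. Nkg7 was lost without either wtIDH1 replicate, Cst7 without wtIDH1 replicate 1, Il10 without wtIDH1 replicate 2, Gzmc without mIDH1 replicate 2 and Rrm2 with DESeq2. Library totals alone gave 335 up and 826 down.

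In NK cell-like cells the granzyme Gzmf (chr14:56205263–56211417) had 236 counts in wtIDH1 and 0 in mIDH1, at least 48-fold lower. Gzmd (167 to 3.79 CPM, −5.25) and Gzmc (609 ± 85.2 to 194 ± 173 CPM, log2 fold change −1.52, SE 0.32, adjusted p = 0.00550) fell, while Ccl5 (3483 ± 553 to 9599.5 ± 5327 CPM, log2 fold change 1.68, SE 0.26, adjusted p = 0.000376) and Nkg7 (1292 to 2438 CPM, 1.13) rose. Here 266 genes rose and 70 fell of 6537, and the interferon-induced Ifi44 (−1.86) fell. S100a8 (5.46) and S100a9 (4.56), which mark neutrophil RNA, rose. Oxidative phosphorylation genes had 15 of 26 up and 20 adjusted over the list alone (median 0.90, adjusted p = 7.94e-21; adjusted p = 0.781 with an estimated correlation). Of 19 type I interferon genes 2 fell and 6 passed adjusted over the list alone (median −0.58, adjusted p = 0.0119; adjusted p = 0.919 with an estimated correlation). That list passed in 3 of the 4 fits that leave out 1 library. The counts were 942 without mIDH1 replicate 1, 140 without wtIDH1 replicate 1 and 141 without wtIDH1 replicate 2. Ifi44 was lost without wtIDH1 replicate 1, Gzmd and Nkg7 without wtIDH1 replicate 2, and Gzmc and Ccl5 with DESeq2. Of the 336 calls 334 separated the libraries, as did 53.9% of tested genes (33.3% by chance), and library totals alone gave 183 up and 270 down.

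In cDC2-like cells 92 genes rose and 8 fell of 7713. Ccl17, a chemokine for CCR4-bearing T cells, rose (419 ± 187 to 1055 ± 348 CPM, log2 fold change 1.57, SE 0.31, adjusted p = 0.0376). Il4i1, an amino acid oxidase of activated antigen-presenting cells, rose (4.86 ± 2.51 to 35.9 ± 5.78 CPM, log2 fold change 3.08, SE 0.48, adjusted p = 0.0215). Hilpda (2.42), Fdps (2.31) and S100a8 (3.30), which marks neutrophil RNA, rose, and Apoe (156 to 45.9 CPM, −1.52), Dusp6 (−1.61) and Mid1 (−2.44) fell. Oxidative phosphorylation genes had 5 of 26 up and 22 adjusted over the list alone (median 0.88, adjusted p = 3.07e-17). Genes of cholesterol synthesis and uptake had 1 of 15 up and 11 adjusted over the list alone (median 0.88, adjusted p = 4.15e-09). For both the adjusted p = 0.817 with an estimated correlation. Each mIDH1 library held only 59 of these cells. The count was 961 without mIDH1 replicate 1, 227 without mIDH1 replicate 2, 1 without wtIDH1 replicate 1 and 0 without wtIDH1 replicate 2, so hardly a call here outlasts the loss of a wtIDH1 library. With no filter for low counts 0 genes passed, and DESeq2 called 187. All 100 calls separated the libraries, as did 54.1% of tested genes (33.3% by chance), and library totals alone gave 35 up and 19 down.

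In cluster 6, which the marker rule named erythroid, 232 genes rose and 112 fell of 3800. Its hemoglobin lay at 10 and 8887 UMIs in the wtIDH1 libraries and 10 and 61380 in the mIDH1 libraries, and 67 of its 849 cells held any. The cluster had a median of 999 UMIs per cell and is no single cell type by its markers, so its genes and lists are left out here. The count was 559 without mIDH1 replicate 1, 154 without wtIDH1 replicate 1 and 0 without wtIDH1 replicate 2, and library totals alone gave 29 up and 28 down. Of the 344 calls 343 separated the libraries, as did 55.1% of tested genes (33.3% by chance).

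Across the 8 classes, cluster 6 included, 85 of 259 tests of fixed lists passed with the preset correlation of camera, and none passed with an estimated correlation. Oxidative phosphorylation genes passed upward in all 8 classes, with medians from 0.61 in neutrophil-like cells to 0.97 in monocyte-like cells. Ribosomal protein genes, which are among the shorter transcripts and were not tested as a list, had medians from 0.67 in neutrophil-like to 1.04 in T cell-like cells. Of them 0 of 82 passed in neutrophil-like, 0 of 81 in microglia-like and 60 of 81 in T cell-like cells. Library totals as the only scaling moved the median gene to −0.43 in neutrophil-like, −0.27 in monocyte-like, −0.32 in macrophage-like and −0.27 in microglia-like cells. It was −0.27 in cDC2-like, −0.25 in T cell-like, −0.22 in NK cell-like cells and −0.40 in cluster 6.

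**Figure D3:**
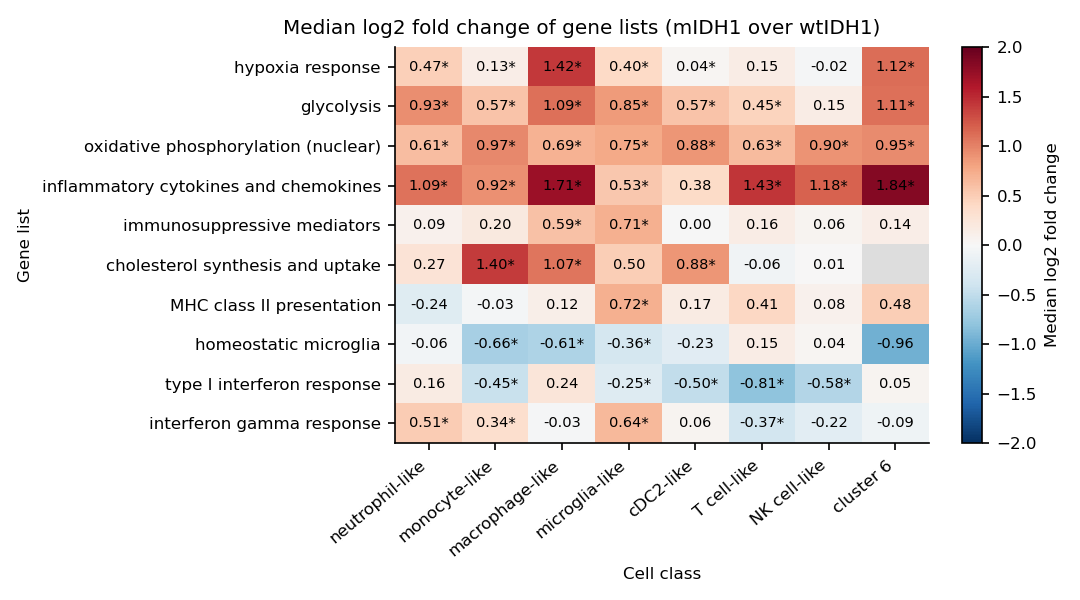
Median log2 fold change of the tested members of fixed lists in each class, with an asterisk on lists that passed camera at its preset correlation, of which none passed with an estimated correlation. With library totals alone the hypoxia medians in monocyte-like and cDC2-like cells turn negative, as do several medians near 0 that did not pass.

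The effect of genotype differed between neutrophil-like and macrophage-like cells for 151 of 10905 genes tested for that difference, and 1128 had p under 0.05. Of the 151, 65 were more positive and 86 more negative in neutrophil-like cells. Chil3 stood at a log2 fold change of 0.29 in neutrophil-like and 4.44 in macrophage-like cells (difference −3.87), where the latter carries the balance between clusters 3 and 4. The iron exporter Slc40a1 stood at −0.77 and −3.87 (3.29), the transcription factor Klf2 at −0.33 and 2.30 (−2.38) and the matrix protein Thbs1 at −1.66 and 0.76 (−2.17). The activin gene Inhba stood at 0.00 and 2.44 (−2.16) and the proteoglycan Sdc4 at −1.52 and 1.58 (−2.81). Hba-a2, a hemoglobin gene, stood at 5.79 and −0.67 (6.67), but of the 3511 hemoglobin UMIs in neutrophil-like cells of mIDH1 replicate 1 a single cell held 2777. Neutrophil RNA in macrophage-like sums enters this test as well. Of 9 genes of that list 5 were more negative in neutrophil-like cells, Retnlg among them (1.56 and 5.14, difference −3.23). By list, 3 of 22 hypoxia genes and 2 of 18 immunosuppressive mediators were more negative in neutrophil-like cells. Of 19 inflammatory genes 2 were more positive and 3 more negative. After subtraction of RNA of other cells 0 of 10740 genes passed, with 641 at p under 0.05. Several differences kept their size or grew, with a wider spread, as for Slc40a1 (3.29, SE 0.39, to 4.02, SE 0.71), Klf2 (−2.38, SE 0.32, to −2.63, SE 0.46) and Thbs1 (−2.17, SE 0.32, to −2.78, SE 0.46). Sdc4 (−1.69, SE 1563000) and Retnlg (1.18, SE 1207000) were left without a usable estimate. DESeq2 called 71, and the count was 282 without mIDH1 replicate 1, 58 without wtIDH1 replicate 1 and 24 without wtIDH1 replicate 2.

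Summed over all kept cells, 1212 genes rose and 719 fell of 13673, which mixes the change in class shares with changes within classes. This count was 38 without mIDH1 replicate 2, 546 without wtIDH1 replicate 1 and 736 without wtIDH1 replicate 2, and DESeq2 called 2939.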

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

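The tests of this part other than the interaction and that of depth per cell were chosen after the results were seen. Cells that no class comparison uses held a signal for Csf3 (chr11:98701263–98703629), which encodes G-CSF. The libraries gave 3 and 0 Csf3 UMIs in wtIDH1 and 84 and 113 in mIDH1, and 167 of these 197 mIDH1 UMIs (84.8%) lay in cluster 17, which is in no named class. Of the 207 cells of that cluster 203 came from mIDH1 libraries (119 and 84). They had few Ptprc UMIs (7.17 CPM), the pan-leukocyte gene, and many of the progenitor and glioma genes Nes (234 CPM) and Sox2 (58.8 CPM). Csf3 stood at 19.0 CPM in them (exact Poisson interval 16.2 to 22.1, counting error only), 13.5 and 27.8 CPM by library, and was seen in 38 cells. Outside the cluster it stood at 0.525 and 1.21 CPM in the mIDH1 libraries, and in the wtIDH1 libraries at 0.1399 CPM and 0, where the floor of 3 counts is 0.145 CPM. In cluster 24, wtIDH1 cells that carry Nes and Sox2, it stood at 1.30 CPM (2 UMIs, 0.157 to 4.69). Cluster 10, which also carries both genes, had 0 Csf3 UMIs in wtIDH1 (0 to 6.00 CPM) and 8 in mIDH1 (6.97 CPM, 3.01 to 13.7). Clusters 24 and 17 also differ in Xist (1415 and 4.10 CPM), so genotype is not separated from the origin of the tumours. Cells of cluster 17 hold 43024 and 38138 UMIs (medians), against 3184 and 2649 for other mIDH1 cells, which raises the chance of seeing Csf3 per cell but not its CPM.

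A difference between groups was tested by the interaction, and 151 genes passed it between neutrophil-like and macrophage-like cells, those of lowest p being Chil3 and Slc40a1. Chil3 leads macrophage cluster 4, so its difference carries the balance of the macrophage clusters. After subtraction of RNA of other cells no gene passed, while Slc40a1 went from 3.29 (SE 0.39) to 4.02 (SE 0.71) and Chil3 from −3.87 (SE 0.36) to −8.14 (SE 2.05). With that SE the size of the Chil3 difference is not well fixed.

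Neutrophil RNA in other classes was weighed first. If stray RNA or doublets bring S100a8 and S100a9 into T cell-like, NK cell-like, cDC2-like cells and cluster 6 (named erythroid), other neutrophil genes must come with them in the ratio of the library's own neutrophils. The UMIs so expected were 118.7% of those observed in mIDH1 (119% for T cell-like, 118% for NK cell-like, 80.7% for cDC2-like cells and 143% for cluster 6), so RNA of neutrophils can account for this rise. In that order the 95% intervals, which cover counting error of the other neutrophil genes, were 97.7 to 144, 72.2 to 182, 41.7 to 141 and 97.5 to 204. In cDC2-like cells the estimate rests on 12 UMIs of those genes, so the part of the rise it covers is not well fixed. A change of these genes within the cells is not needed to reach the observed counts. In monocyte-like, macrophage-like and microglia-like cells, which are outside this pattern, the same percentages were 104, 93.2 and 85.1 in mIDH1 and 29.98, 32.0 and 42.3 in wtIDH1, where neutrophil RNA falls short of the observed counts.

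Higher oxidative phosphorylation transcripts in all 8 classes were weighed next. Between cells of like UMI total the log2 ratio of the list's share was 0.5116 (median of the 8 classes), against 0.5416 unmatched, and it stayed above 0 in all 4 pairs of libraries in all 8 classes, so depth per cell is not the whole cause. In neutrophil-like cells it fell from 0.2539 to 0.1283 when matched, so depth carries part of it there. Against genes of like length and level the list's median log2 fold change fell from 0.818 to 0.2779, with a lower quartile above 0 in 3 classes, so transcript length may account for part of it and this test cannot tell. Differences between the 2 mIDH1 libraries followed length as well, with rank correlations from −0.3455 in monocyte-like to −0.0556 in neutrophil-like cells over the 8 classes. Mitochondrial UMIs also differed by genotype in T cell-like cells (medians of 6.04 and 5.93% in wtIDH1, 4.74 and 3.64% in mIDH1) and NK cell-like cells (5.71, 5.66, 4.75 and 3.44%), which was not tested as an explanation. Genotype as the cause was not tested apart from the libraries that carry it.

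Higher hypoxia and glycolysis genes in macrophage-like cells were weighed last. The lowest of the list medians within cluster 3 and within cluster 4 was 0.08855 (hypoxia in cluster 4), but the clusters were drawn from the expression of such genes, so this cannot tell a change in cluster balance from a change in the cells. After subtraction of neutrophil RNA the hypoxia median was 1.436, and against genes of like length and level 1.241, so neither neutrophil RNA nor transcript length is the whole cause. Whether genotype moves cells between these macrophage states or changes genes within them was not settled.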

How the results depend on the processing

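With 2 libraries per genotype every count of calls rests on single libraries, and shallow classes find only large changes. The genes tracked here were chosen because they passed the main test, and nearly all genes so called separated the libraries by genotype. That they keep their direction with a library left out was thus nearly fixed by that choice. Of the values tracked for named genes, 315 kept their direction and side of the threshold without mIDH1 replicate 2 and 136 were lost, against 412 and 39 without mIDH1 replicate 1, 328 and 120 without wtIDH1 replicate 1 and 257 and 193 without wtIDH1 replicate 2. The same counts were 337 and 29 with DESeq2, 432 and 20 with relative log normalization, 377 and 75 with library totals, 436 and 12 with thinned sums and 361 and 67 after subtraction of RNA of other cells. Cluster 6, named erythroid, gave no result with at least 500 genes per cell, and microglia-like cells none at resolution 0.5.

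Counts of changed genes moved as follows, and where nothing else is said the cause was not tested. Neutrophil-like cells (29): DESeq2 169, relative log normalization 50, library totals 246, no filter for low counts 328, block 166, resolution 2.0 212, at least 500 genes 262, at most 5% mitochondrial UMIs 80, doublets kept 69, thinned 215, subtraction of RNA of other cells 0, the first version of it 0, and 36 to 829 with a library left out. Monocyte-like cells (693): library totals 1340, no filter 1307, block 1264, resolution 2.0 1166, at most 5% mitochondrial UMIs 1646, doublets kept 1276, first subtraction 0 and 77 to 969. Macrophage-like cells (1070): library totals 1753, no filter 2191, block 551 and 397 to 1838. Microglia-like cells (102): no filter 291, at most 5% mitochondrial UMIs 46, thinned 173, subtraction 27, first subtraction 0 and 54 to 370. The cDC2-like cells (100): DESeq2 187, library totals 54, no filter 0, block 494, at least 500 genes 155, at most 5% mitochondrial UMIs 198, doublets kept 153, thinned 197, first subtraction 16 and 0 to 961. T cell-like cells (667): library totals 1161, no filter 1282, block 1243 and 244 to 1811. NK cell-like cells (336): DESeq2 173, at most 5% mitochondrial UMIs 169, doublets kept 194 and 140 to 942. Cluster 6 (344): library totals 57, resolution 0.5 208, resolution 2.0 1502 and 0 to 559. All cells summed (1931): DESeq2 2939 and 38 to 2604. Monocyte-like and macrophage-like cells summed together gave 744. The first subtraction took 96.4% of the UMIs of microglia-like cells of mIDH1 replicate 1 and at most 40.4% of any other sum. The difference between classes (151) gave 71 with DESeq2, 24 to 282 with a library left out and 0 after subtraction. Of the 85 list calls 0 held with an estimated correlation and 1 with fry.

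Of class shares 1 passed, against 3 with trimmed mean normalization, 0 to 3 with a library left out, 4 with at least 500 genes, 2 with doublets kept, and 4 with neutrophil precursors and the unnamed neutrophil cluster added at resolution 2.0 or with at least 500 genes. The neutrophil-like share passed with trimmed mean normalization (log2 fold change 3.52), the block (2.96), at least 500 genes (3.07), at most 5% mitochondrial UMIs (2.89), doublets kept (3.08), and the wider class at resolution 2.0 (2.90) or with at least 500 genes (2.92). The cDC2-like share did not pass with the block (−1.71) or with at most 5% mitochondrial UMIs (−1.60), nor without wtIDH1 replicate 1 (−1.70) or 2 (−1.72). The cause was not tested for any of these.

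Directions turned in 15 cases. In monocyte-like cells S100a9 fell to −10.95 and S100a8 to −0.51 after subtraction, and to −10.75 and −0.047 with Hilpda at −0.11 in its first version. The subtraction left S100a9 with no mIDH1 count, so the size of its fold means nothing. Stfa2l1 in macrophage-like cells, one of the genes that set the size of the subtraction, went to −2.93 and −2.83. Hspa1b in microglia-like cells went to −0.013. With doublets kept Ccl17 in monocyte-like cells went to −0.57 and Fn1 in T cell-like cells to −1.29, and with at least 500 genes Apoe in T cell-like cells went to −0.029. At resolution 0.5 Chst1 (0.014), C1qa (0.17), Il4ra (0.13) and H2-K1 (0.019) turned in the class named erythroid, which there holds 512, 578, 425 and 241 cells and so is not cluster 6 alone. The cause was not tested for these.

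The replicate numbers do not pair the samples by the labels. Deviations from the group means correlated between libraries of the same number at −0.0814 in neutrophil-like, 0.127 in monocyte-like, −0.204 in macrophage-like, −0.177 in microglia-like, 0.192 in cDC2-like, −0.0398 in T cell-like, 0.00689 in NK cell-like cells and 0.165 in cluster 6, so the block gives counts only. With it 29, 693, 535, 88, 100, 667, 330 and 344 of the main calls passed again in that order.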

Other observations

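The comparisons below were chosen after the results were seen. Monocyte-like cells held 2 clusters. Cluster 13, led by Ace, Ear2 and Treml4 as in patrolling monocytes, held 89, 81, 93 and 94 cells per library, while cluster 0 held 657, 387, 192 and 183. Within it 428 genes rose and 157 fell of 6544, and within cluster 0, led by Ly6c2 and Ccr2 as in inflammatory monocytes, 402 rose and 128 fell of 9136. The inflammatory list had medians of 1.02 in cluster 13 and 0.93 in cluster 0, oxidative phosphorylation 0.96 and 0.91, and cholesterol synthesis and uptake 0.28 and 1.57. In macrophage-like cells Vcan (24.1 to 138 CPM, 2.84), a gene of recruited monocytes, rose in the class. Within clusters 3 and 4 it did not pass (0.49 and 0.71), so the class value carries the cluster balance. Within cluster 4 of the macrophage-like cells 26 of 28 type I interferon genes were higher (median 0.65, none past the threshold), and within cluster 3 10 of 28 were (−0.21).

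Cells outside the immune classes differed between the genotypes as well. Cluster 24, led by Serpinh1, Esm1 and Igfbp3, held 17 and 34 wtIDH1 cells and no mIDH1 cell, while cluster 17, led by Rhox5, Wfdc2 and Krt18, held 4 and 0 wtIDH1 cells and 119 and 84 mIDH1 cells. Both carried Sox2 (154 and 58.8 CPM) and Nes (217 and 234 CPM) with little Ptprc (8.44 and 7.17 CPM). Nras stood at 1809 and 1847 CPM in them. Xist, which is read from the inactive X chromosome, stood at 1415 CPM in cluster 24 (exact Poisson interval 1356 to 1476) and at 4.10 CPM in cluster 17 (2.87 to 5.67). Cluster 10 held 141, 110, 129 and 148 cells and showed the same contrast, with Xist at 220 CPM in wtIDH1 and 25.3 CPM in mIDH1 and Cdkn2a at 0 and 524 CPM. Idh1 stood at 20.12 CPM in cluster 24 (13.67 to 28.55) and at 104.4 CPM in the mIDH1 cells of cluster 17 (97.75 to 111.4). In cluster 10 it stood at 27.64 CPM in wtIDH1 and 143.7 CPM in mIDH1. These counts do not tell mutant from wild-type transcripts. Csf2, which encodes GM-CSF, stood at 5.84 CPM in cluster 24 and 6.26 CPM in cluster 17, and Csf1 at 76.6 and 33.5 CPM. Csf3 stood at 1.30 CPM in cluster 24 (2 UMIs, 0.157 to 4.69) and 19.0 CPM in cluster 17. Immune cells of both genotypes carried Xist (cluster 16 at 546 and 455 CPM in wtIDH1 and mIDH1), and Y-linked genes gave 0, 4, 17 and 7 UMIs per library, which gives no sign of hosts of different sex. Why Xist is low in cluster 17 was not tested, and tumour origin is not separated from genotype in these values. The intervals cover counting error only.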
